A study of Homo sapiens with 4 samples.

How the data were processed

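Circular RNAs (circRNAs) are closed RNA loops made when a downstream splice site is joined to an upstream one, and they are counted from reads that cross this back-splice junction. They were profiled in HepG2, an established human liver cancer cell line, in 2 groups of 2 libraries each: cells labelled normal and cells kept without glucose for 24 h. Per the labels' protocols, total RNA was extracted with TRIzol, ribosomal RNA was removed with Ribo-Zero, linear RNA was digested with RNase R, and libraries were made with a stranded total RNA kit. Digestion enriches circRNAs by an amount that was not measured here, so levels between libraries are relative to the circRNA reads of each library. The labels do not say whether the replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

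The analysis started from 1 table of 11666 circRNAs with read counts and depth-scaled values (CPM) for the 4 libraries. The count columns hold whole read counts that the authors deposited without normalization. No library holds a value of 1, and the smallest value above 0 is 2 in each. No source used here states a minimum, so what a listed 0 means is not known. The CPM columns were deposited under a header that calls them tpm, and each value equals the count divided by its column total times 1000000, within 4.22e-06, so no length term is in them. The submitters' processing notes name the hg19 genome build and DESeq2, without a version or a role. The aligner, the circRNA caller and the filters are not given in the sources used here. The circRNAs carry either a circBase identifier (7525 rows; circBase is a public circRNA database) or a running number (4141 rows). The table does not pair identifiers with genes or coordinates, and no reference table used here did so. Host genes, positions and exons are therefore not reported, and the circRNA of EPB41 that the series title names was not matched to a row.

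Counts were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3), with TMM factors and filterByExpr at its defaults. Benjamini-Hochberg adjustment ran over the 2803 circRNAs that passed. Library sizes were the reads of each library in the circRNAs that passed, from 47232 to 123886, and not the planned column totals. The threshold was an adjusted p of 0.05. All 4 libraries entered 1 fit with the group as its term. The design, its alternatives and the rule for named circRNAs were fixed before the data were examined. The rule was to name the 12 circRNAs with the smallest p in each direction among calls, or 5 per direction where fewer pass, and the 5 with the highest mean normalized count. Because identifiers without gene names carry little for a reader, the text names 2 per direction and the 5 most abundant. Planned tests on counts summed per host gene, on usage within a host gene, on EPB41 circRNAs and on 15 host gene lists were not run, since they need host genes. A fitted fold change is not printed for a circRNA listed at 0 throughout a group, because it depends on the prior count. A printed standard error is the absolute log2 fold change divided by the square root of the F statistic of the test.

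The alternatives fixed beforehand were DESeq2 1.42.0, RLE size factors, total reads only, no filter, a filter of at least 10 reads in 2 libraries, a robust dispersion, the replicate number as a block, limma 3.58.1 on log2(CPM + 1) and on log2(CPM + 0.1), and each library left out in turn. With 1 library left out the tested set changed as well, since the filter then passed 3174 to 3938 circRNAs. A crossed pairing was added after seeing the data. So was a fit limited to circRNAs with reads in all 4 libraries, alone and combined with other settings. The limitation to reads in all 4 libraries removes circRNAs that were lost from, or gained in, a whole library. In the alternative with total reads only, the totals were also those of the circRNAs that passed the filter.

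Each pair of libraries was compared by the common negative binomial dispersion (edgeR, TMM), whose square root is the coefficient of variation beyond counting noise, over 1644 circRNAs with reads in all 4 libraries and a mean of at least 100 CPM. Intervals are 95% bootstrap intervals from 200 resamplings of circRNAs. A chi-square test of the counts of each pair ran over the same circRNAs. These comparisons were also added after seeing the data. Single values between groups were compared by exact 2-sided permutation tests, and 2 libraries against 2 cannot give a p below 0.333.

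The test was checked on simulated data with 200 changed circRNAs. With counts drawn at the dispersion of the tested set, 0.336, 2241 of the 2803 simulated circRNAs passed the filter. Of the changed ones that passed, the test called 0 of 55 with a 2-fold change, 0 of 47 with a 4-fold change and 1 of 52 with an 8-fold change, with 0 false calls. At the dispersion of the circRNAs with reads in all 4 libraries, 0.0388, it called 12 of 59, 52 of 60 and 56 of 57 of those changed 2-, 4- and 8-fold, with 8 false calls among 1738 unchanged ones. These counts also leave out changed circRNAs that failed the filter. In each simulation all circRNAs shared 1 dispersion, which those in the data need not do. The shares called may therefore overstate what the fits to the data could call. Depth per library ran from 58776 to 166071 circRNA reads.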

Results

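CircRNAs of HepG2 cells were counted in 2 normal libraries and 2 libraries from cells without glucose for 24 h. The question was which circRNAs differ in level when the cells lose glucose. Normal replicates 1 and 2 held 133083 and 166071 circRNA reads, and glucose-free replicates 1 and 2 held 102420 and 58776. Of the 11666 circRNAs in the table, 10989 had reads in at least 1 library, 3964 had reads in all 4, and 677 were listed at 0 throughout. Most circRNAs were shallowly covered, with a median of 4 to 7 reads among those listed in a library.

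Fewer distinct circRNAs were listed without glucose, in libraries that were also shallower. Normal libraries listed 9508 ± 156 circRNAs and glucose-free libraries 6654 ± 816 (SD, n = 2 each). With every library thinned to 58776 reads and at least 2 reads required, the smallest value above 0 in the table, the numbers were 6618 ± 112 and 6005 ± 101 (SD, n = 2 each). Both glucose-free libraries lay below both normal libraries, which an exact permutation test cannot separate from chance with 2 libraries per group (2-sided p = 0.333, the smallest possible). CircRNAs without a circBase identifier took 16.2% ± 0.473 of reads in normal and 15.1% ± 0.131 in glucose-free libraries (SD, n = 2 each; exact permutation p = 0.333). The 100 most abundant circRNAs of each library took 24.0% ± 0.0615 and 26.4% ± 1.08 of reads (SD, n = 2 each; exact permutation p = 0.333).

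No circRNA passed the test between glucose-free and normal cells. Of 2803 circRNAs tested with edgeR's quasi-likelihood test, 0 were past an adjusted p of 0.05, and the smallest adjusted p was 0.964. At an unadjusted p under 0.05 there were 29 circRNAs higher and 36 lower without glucose, 65 in all, where chance alone would give about 140.2. The split depended on the method: it was 71 higher and 22 lower with limma on log2(CPM + 1), 87 and 23 on log2(CPM + 0.1), and 69 and 304 without a filter, each with 0 past an adjusted p of 0.05. DESeq2 gave 0 past an adjusted p of 0.05 among 10989 circRNAs, with a smallest adjusted p of 0.0567, and 63 at an unadjusted p under 0.05. Among circBase circRNAs with reads in both groups the median log2 fold change was -0.03, with 1130 values above 0 and 1232 below. Among the numbered circRNAs it was 0.01, with 213 above and 209 below. The TMM factors place the typical fold change near 0, so these values cannot show a shift common to most circRNAs.

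Among circRNAs with higher values without glucose, hsa_circ_0074828 and hsa_circ_0003047 had the smallest p. The first was listed at 0 in both normal libraries and had 17 and 12 reads in glucose-free replicates 1 and 2 (edgeR adjusted p = 0.999). For hsa_circ_0003047 the level was 90.2 ± 0.11 CPM in normal and 344 ± 52.7 CPM in glucose-free cells (SD, n = 2 each), a log2 fold change of 1.82 with a standard error of 0.36 (edgeR adjusted p = 0.999). It passed the adjusted threshold, at a log2 fold change of 2.02, among circRNAs with reads in all 4 libraries when glucose-free replicate 2 was left out, and at 1.82 there with the replicate number as a block. Among those with lower values, hsa_circ_0002484 had 146 and 207 reads in the normal libraries and was listed at 0 in both glucose-free libraries (edgeR adjusted p = 0.964). The next, hsa_circ_0001064, had 65 and 93 reads in the normal libraries and was also listed at 0 in both glucose-free libraries (edgeR adjusted p = 0.999). Both circRNAs listed at 0 without glucose passed the adjusted threshold when either glucose-free library was left out, and 19 of the 65 circRNAs at an unadjusted p under 0.05 were listed at 0 in both libraries of a group.

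The 5 most abundant circRNAs differed by less than 2-fold between the groups, and none passed the test of all 2803 circRNAs. The most abundant, hsa_circ_0084615, stood at 13351 ± 943 CPM in normal and 19258 ± 5339 CPM in glucose-free cells, 1.44 times the normal mean (SD, n = 2 each). The level of hsa_circ_0060927 was 7058 ± 67.0 and 12045 ± 3705 CPM, a ratio of 1.71, and that of hsa_circ_0008285 was 8045 ± 1448 and 10558 ± 1169 CPM, a ratio of 1.31 (SD, n = 2 each). Lower means without glucose were found for hsa_circ_0004405, at 0.675 times, and hsa_circ_0007158, at 0.625 times the normal mean. The edgeR adjusted p was 0.999 for each of the 5. Among circRNAs with reads in all 4 libraries, hsa_circ_0060927 (log2 fold change 1.01) and hsa_circ_0007158 (-1.07) passed the adjusted threshold when glucose-free replicate 2 was left out, and hsa_circ_0060927 (0.65), hsa_circ_0004405 (-0.67) and hsa_circ_0007158 (-0.79) passed it in all 4 libraries with the replicate number as a block. The block leaves 1 residual degree of freedom, and no label says that the replicate numbers mark a pairing. For each of the 5, glucose-free replicate 1 lay farther from the normal mean than glucose-free replicate 2.

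**Figure D1:**
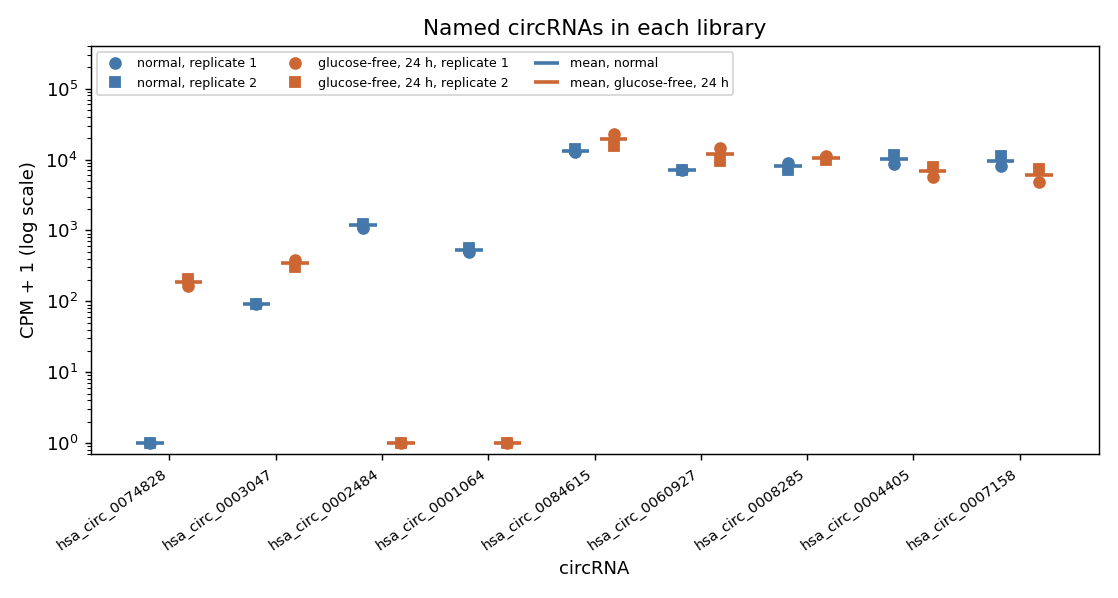
CPM + 1 on a log scale (y) for each named circRNA (x), with points for single libraries (circles replicate 1, squares replicate 2) and bars for group means. The circRNAs at the bottom of the axis are listed at 0 in both libraries of a group, while the 5 most abundant, on the right, differ by less than 2-fold.

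The closest libraries came from different groups. Over 1644 circRNAs with reads in all 4 libraries, the dispersion was 0.0319 (95% bootstrap interval 0.0253 to 0.0419) between the normal libraries and 0.0458 (0.0371 to 0.0578) between the glucose-free libraries. Between normal replicate 1 and glucose-free replicate 2 it was 0.00234 (0.000729 to 0.00401), and with zeros included it was 0.115. The value of 0.00234 corresponds to a coefficient of variation of 4.83%. It does not show variation beyond counting noise, since the chi-square of this pair lay below its degrees of freedom. Over the circRNAs with reads in all 4 libraries, the counts of these libraries of different groups agree within sampling noise, with a chi-square of 1487.4 on 1643 degrees of freedom (p = 0.997). The other 5 pairs had 2.27 to 5.76 times as much chi-square as degrees of freedom. The other pairs across the groups had dispersions of 0.0572 (normal replicate 2 with glucose-free replicate 2, interval 0.0469 to 0.0696, which overlaps that of the glucose-free pair), 0.0650 (both replicates 1) and 0.104 (normal replicate 2 with glucose-free replicate 1, interval 0.0928 to 0.116). Leaving out normal replicate 1 left 0 calls in the test of all circRNAs, and leaving out glucose-free replicate 2 gave 71, of which 70 were lower without glucose and 70 were listed at 0 in the remaining glucose-free library. Leaving out glucose-free replicate 1 gave 24, all lower and all listed at 0 in the remaining library.

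**Figure D2:**
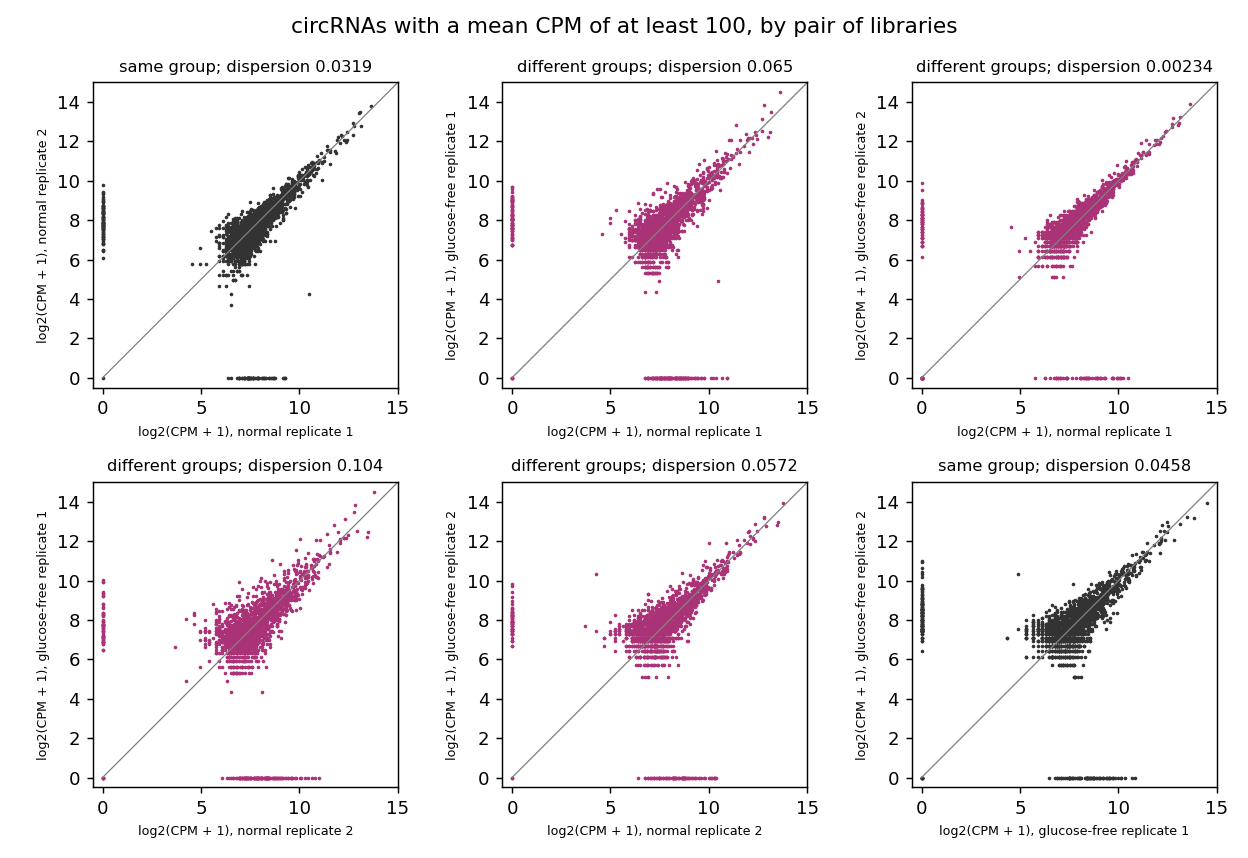
Each panel plots log2(CPM + 1) of 2 libraries against each other for the circRNAs with a mean of at least 100 CPM (black, same group; purple, different groups; grey line, equal values), with the dispersion over circRNAs with reads in all 4 libraries. The tightest panel is normal replicate 1 against glucose-free replicate 2, at 0.00234, and each panel has points at 0 in 1 library that lie far from the rest.

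Many abundant circRNAs were listed at 0 in some libraries. At the rate seen in the libraries where they had reads, 1172 circRNAs were expected to have at least 10 reads in every library, and 271 of them (23.1%) were listed at 0 in at least 1. The zeros numbered 88 and 47 in normal replicates 1 and 2 and 115 and 83 in glucose-free replicates 1 and 2. Of the 52 circRNAs listed at 0 in exactly 2 libraries, 10 were at 0 in both glucose-free libraries and 1 in both normal libraries, while 29 were at 0 in normal replicate 1 and glucose-free replicate 2. As an example chosen after its values were seen, hsa_circ_0001839 had 259, 332 and 116 reads in normal replicates 1 and 2 and glucose-free replicate 2 and was listed at 0 in glucose-free replicate 1, where 202 reads were expected.

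**Figure D3:**
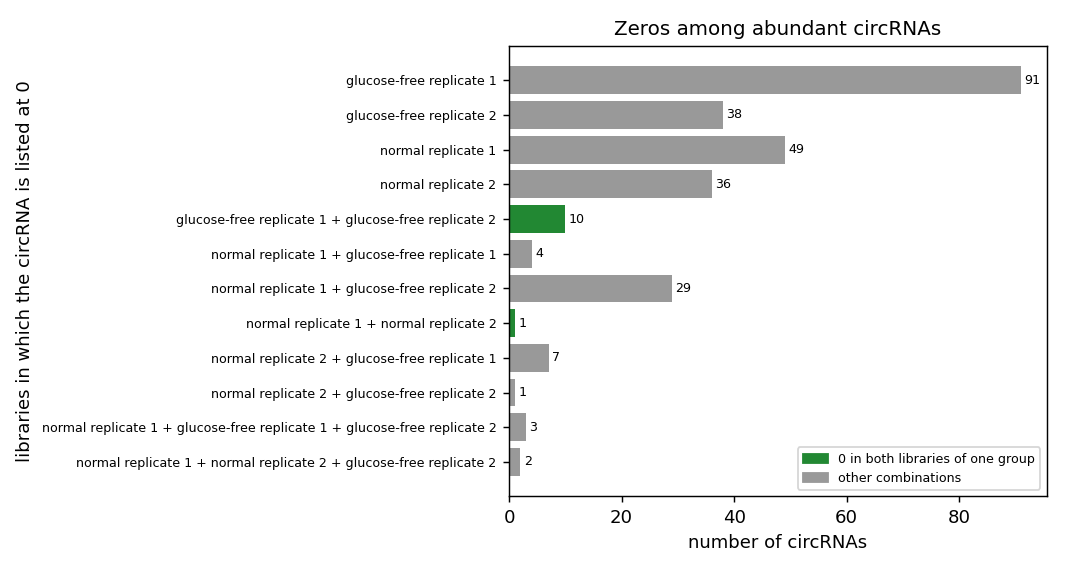
Number of abundant circRNAs (x, counts) listed at 0, by the libraries in which they are at 0 (y); green bars are zeros in both libraries of one group and grey bars all other combinations. The 10 and 1 circRNAs that follow the groups are fewer than the 29 at 0 in normal replicate 1 and glucose-free replicate 2.

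With these zeros left out, the spread was smaller, and still no circRNA passed the test. Among 2131 tested circRNAs with reads in all 4 libraries, a set chosen after seeing the data, the dispersion was 0.0388, against 0.336 for all tested circRNAs. edgeR's quasi-likelihood test called 0 at an adjusted p of 0.05, with a smallest adjusted p of 0.0868 and 120 higher and 67 lower at an unadjusted p under 0.05, 187 in all, where chance alone would give about 107. Without normal replicate 1 the same test called 23 (21 higher, 2 lower), and without glucose-free replicate 2 it called 61 (46 higher, 15 lower). Without normal replicate 2, or without glucose-free replicate 1, it called 0, and with the replicate number as a block it called 17 (15 higher, 2 lower). In these fits with 1 library left out, the lone library is assumed to vary like the other group. These fits also tested more circRNAs than the 2131, from 2358 without normal replicate 2 to 2783 without glucose-free replicate 1.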

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

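The count of 0 circRNAs past the adjusted threshold was also found with RLE size factors, total reads only, no filter, the stricter filter, the robust dispersion, DESeq2 and limma with either pseudocount. The same-numbered libraries deviated from their group means with a correlation of -0.173 over the tested circRNAs. The closeness of normal replicate 1 and glucose-free replicate 2 by itself pulls this value below 0. It therefore cannot show whether the numbers pair the libraries. The replicate block, fixed beforehand, and the crossed pairing, added after seeing the data, each gave 0 calls. Limited to circRNAs with reads in all 4 libraries, the replicate block gave 17 calls, among them hsa_circ_0003047, hsa_circ_0060927, hsa_circ_0004405 and hsa_circ_0007158. That fit leaves 1 residual degree of freedom, and the crossed pairing was not run on this set. An unadjusted p under 0.05 with an absolute log2 fold change of at least 1 selected 55. Leaving out 1 library gave 0 to 71 calls: 71 without glucose-free replicate 2, 24 without glucose-free replicate 1 and 0 without either normal library. Among circRNAs with reads in all 4 libraries, leaving out 1 library gave 0 to 61, with 23 without normal replicate 1. Thinning to the shallowest library left 6696.9 and 6538.4 circRNAs in normal replicates 1 and 2 and 5933.8 in glucose-free replicate 1, as means over 100 draws. A minimum of 5 reads left 5736 and 6571 in normal replicates 1 and 2 and 3007 in glucose-free replicate 2, with 4496 in glucose-free replicate 1. Of the 9 named circRNAs, 6 passed the threshold in 1 or 2 alternatives and none in the opposite direction, and hsa_circ_0084615 changed sign once, uncalled. With zeros included, the dispersions rose to between 0.115 and 0.458, and that of normal replicate 1 against glucose-free replicate 2 was again the lowest of the 6, but normal replicate 2 and glucose-free replicate 2, at 0.269, lay below the glucose-free pair, at 0.375. Depth may limit what can be seen, with 58776 reads over 6077 circRNAs in the shallowest library, but its effect on the calls was not tested. In the simulations, the share of changed circRNAs called depended on the dispersion. Alternatives for host genes, usage within host genes, host gene lists and EPB41 circRNAs were not run.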

Other observations

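Every test in this part except the thinning test of the dispersions and the count of zeros among calls was chosen after the result was seen.

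Normal replicate 1 and glucose-free replicate 2 differed less than libraries of one group. Low depth of glucose-free replicate 2 does not account for this: with every library thinned to its depth, the dispersion of each other pair stayed at or above 0.022 in 20 draws, against at most 0.00428 for this pair. Thinning is not expected to lower a dispersion, so the draws check only that the estimate holds at low depth. At its own depth, glucose-free replicate 2 had dispersions of 0.0572 with normal replicate 2 and 0.0458 with glucose-free replicate 1. Labels swapped between the groups are argued against by the partner pair, normal replicate 2 and glucose-free replicate 1. Over circRNAs with reads in all 4 libraries, the dispersion of the partner pair, 0.104, was the largest of the 6. With zeros included it was 0.430, below the 0.458 of both replicates 1 but above both same-group pairs (0.261 and 0.375). Over circRNAs with reads in all 4 libraries, one library deposited under 2 names may explain the counts, since chi-square per degree of freedom was 0.905. It does not by itself account for 103 of 1172 abundant circRNAs (8.79%), at 0 in only one of the 2 libraries, which that set leaves out. Nor does it by itself account for the numbers listed at equal depth. Thinned to 58776 reads, normal replicate 1 held 6610 to 6792 circRNAs with at least 2 reads over 100 draws. Glucose-free replicate 2 listed 6077. One wrong label, or a shared culture or library batch, cannot be told apart from it by the dispersion of 0.00234, because no labelled batch or known treatment marker places either library. A weak response of glucose-free replicate 2 is argued against as the whole cause: it would leave the pair about as far apart as the normal libraries, whose interval was 0.0253 to 0.0419, and the upper end for this pair was 0.00401. That comparison rests on 1 pair of normal libraries, and a weak response beside another cause is open.

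Abundant circRNAs were listed at 0 in some libraries. Sampling at the depth of the library is argued against: there were 333 zeros, and 1000 draws gave at most 8 at the largest dispersion between any 2 libraries over circRNAs with reads in all 4 libraries (0.104), and at most 77 at the largest with zeros included (0.458). Under the labels as given, loss or gain with glucose deprivation does not account for the 129 of the 271 circRNAs that were at 0 in one normal library and had reads in the other. For the other 142, a real change is open. Of these, 11 were at 0 in exactly the libraries of one group, the lower circRNAs with the smallest p among them. A further 91 and 38 were at 0 in glucose-free replicate 1 or 2 alone. Since 49 and 36 were at 0 in normal replicate 1 or 2 alone, the 91 and 38 need not reflect glucose loss. Nor need the 11, since 29 circRNAs were at 0 in normal replicate 1 and glucose-free replicate 2, which belong to different groups. How many unrelated zeros would coincide in the libraries of a group was not computed. Whether the caller or a merging step set these values to 0 was not tested.

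Calls appeared when glucose-free replicate 2 was left out. Zeros in the remaining glucose-free library may explain most of them, since 70 of the 71 calls were at 0 there. The prediction also required few calls among circRNAs with reads in all 4 libraries, and 61 were made there, so differences of glucose-free replicate 1 from both normal libraries remain that zeros do not explain. With 1 glucose-free library in that fit, a response to glucose loss and a feature of that library cannot be told apart.

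The split of the 4 libraries by treatment gave 65 circRNAs at an unadjusted p under 0.05. Setting normal replicate 1 and glucose-free replicate 2 against the other 2 libraries gave 117, and setting replicate 1 against replicate 2 gave 12. Each lies below the 140.2 or so that chance alone would give, so their order does not show that a split holds real differences. The split with 117 puts the closest libraries together, so its count partly restates their closeness. Among circRNAs with reads in all 4 libraries the order differed, with 187 by treatment and 27 by replicate number. Normal replicate 1 and glucose-free replicate 2 against the others gave 158, with 1 past an adjusted p of 0.05 in edgeR, against 0 by treatment. Chance alone would give about 107 in that set.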
